A study of Mus musculus with 4 samples.

How the data were processed

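RNA selected by polyA was measured in 4 libraries of mouse bone-marrow-derived macrophages, which the labels give as separate biological samples of 1 group. Replicate numbers follow the labels. Because there is 1 group, no between-condition comparison was made: levels are means with the SD over libraries (n = 4), lists of genes were compared within libraries, and libraries were compared with each other. Which genes to name, the gene lists, the comparisons, their tests and most alternatives were chosen before the data were examined. Protocol documents were not used here.

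For each library the authors gave a gene-level table, a transcript-level table with the same kinds of column (the first quantification) and another transcript-level table (the second quantification). The records deposited with them name the assembly mm10 and the annotation GENCODE M21, and derive the first from alignments to the transcriptome and the second directly from the reads. They do not name the programs; the column names are those that RSEM writes for the first and kallisto for the second. Per the file headers the first holds an expected count, which is not normalised, per gene or transcript. The deposited TPM values are scaled by the authors to the same sum in each library, with spike-in and control sequences in the total. The deposited FPKM values are scaled by transcript length and by the number of fragments, and the deposited share of each transcript in its gene is in percent. The deposited records also give 6 read files for replicates 1 and 2 and 4 for replicates 3 and 4. The gene-level tables hold 81881 entries, of which 55536 are Ensembl genes and were used. The 26248 entries with numeric identifiers and the 96 ERCC spike-ins had no count in any library. The phage phiX, a sequencing control, held 0.139%, 0.293%, 0.0790% and 0.0848% of all counts in replicates 1 to 4. Transcripts in both quantifications numbered 141767, and these were summed per gene for the comparison between them.

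Expected counts on genes came to 26613690, 23167140, 41453162 and 34946569 in replicates 1, 2, 3 and 4, and 17129, 17479, 18473 and 17339 genes had a value above 0. The 10 genes with the most counts took 17.7%, 13.7%, 12.2% and 14.3% of them. Mitochondrial genes held 1.94%, 2.79%, 4.77% and 3.99% of TPM and ribosomal RNA genes 7.29%, 2.88%, 1.51% and 2.91%. A count of 0 allows up to 3 counts, which is 0.113, 0.129, 0.0724 and 0.0858 CPM (counts scaled to library size) in replicates 1 to 4. These floors cover counting error only, since reads from PCR are not independent molecules. Counts were rounded for the count models.

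A gene counted as detected at 1 TPM or more in each library. List levels are the median of log2(TPM + 0.1) over members. The lists, with 29 fixed in all, were immediate-early transcription factors, NF-kB feedback regulators, reported tolerance regulators, cytokines, chemokines, interferon-stimulated genes, the TLR4 pathway, other pattern-recognition receptors, classical and alternative activation, antigen presentation, macrophage identity, osteoclast markers, proliferation, glycolysis, cholesterol synthesis and efflux, oxidative stress response, heat shock proteins, circadian clock genes, sex-linked genes, and RNA quality and mitochondrial transcripts. Markers of neutrophils, dendritic cells, T cells, B cells, NK cells, mast cells and basophils, erythroid cells and stroma were also fixed and pooled as other cell types (82 measured genes). A list of eosinophil markers was added after seeing the data. Of the list entries 6 (5 symbols, Irg1 in 2 lists) were absent from the annotation, among them older names of genes also listed by a newer one, and 1 symbol had several identifiers.

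For 6 pairs of lists the difference of medians was taken in each library. It was tested by an exact two-sided sign-flip test over the 4 libraries, whose smallest p is 0.13, and by a two-sided permutation test that reassigned genes between the lists 100000 times (seed 7; smallest p 2e-05), adjusted over the 6 differences by Benjamini-Hochberg at 0.05. Genes are not independent replicates, so the permutation p describes the lists and not the replicates. Tests are in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots in matplotlib 3.10.9.

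Variable genes were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM normalisation, a trended dispersion with an intercept only, then the deviance of each gene over the 4 libraries against that trend, with 3 degrees of freedom, adjusted by Benjamini-Hochberg at 0.05. The common biological coefficient of variation was 22.4%. Each library's role was counted as the one farthest from the others. The split by read files was tested by edgeR's quasi-likelihood test and by DESeq2 1.42.0, 2 libraries against 2. The quantifications were compared by limma 3.58.1 on the per-library log2 difference, second minus first, with the variance tied to level; a gene was called at an adjusted p up to 0.05 and at least 1 log2 unit, among genes with a mean of at least 1 TPM in either. The prior degrees of freedom were estimated as infinite, so standard errors came from the trend alone and not from the gene's own spread. Isoform counts took protein-coding genes at 1 TPM or more in each library with several annotated transcripts.

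Named genes were, for levels, the 15 with the highest mean TPM, the 3 highest of each list and 31 fixed genes of the Lipid A response, 108 in all. For variable genes they were the 20 with the smallest adjusted p and each list member past the threshold, 69 in all. For quantifications they were the 8 called genes with the largest difference each way among those with at least 10 TPM in the higher one, and called list members. For isoforms they were fixed genes with 2 transcripts above 10%. Genes named in the closing section for lying beside another were chosen after their values were seen, and not every such gene is reported here.

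The alternatives were pseudocounts of 1 and 0.01, list members at 1 TPM or more, CPM, which is not divided by length, list means, the second quantification, detection at 0.5 or 5 TPM or by FPKM, DESeq2 size factors, no filter, a mean count of at least 50, a common dispersion, no dispersion, DESeq2's dispersion trend, filters of 0 and 5 TPM for the quantifications, all transcripts, a leading transcript at least 1.5 times the next, and leaving out each replicate. Chosen after seeing the data were TPM rescaled without ribosomal RNA and mitochondrial genes, variable genes without ribosomal RNA, centring and an untied variance for the quantifications, and the alternatives for single genes and single lists.

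The tests were tried on simulated data. With 1 library changed, the spread test found 6 of 67 genes changed 2-fold (8.96%), 45 of 67 changed 4-fold (67.2%) and 61 of 66 changed 8-fold (92.4%). It made 3 false calls among the unchanged genes of 11484 tested. For 2 libraries against 2, edgeR found 24 of 67, 61 of 67 and 65 of 66 with 15 false calls, and DESeq2 25, 60 and 63 with 19. These counts were drawn for each gene at the fitted dispersion trend, with no scatter of genes around it. The shares found and the false calls therefore need not hold for the real libraries. For the quantifications limma found 33 of 67, 67 of 67 and 66 of 66 with 0 false calls, from simulated values whose pairs differed by noise alone. The permutation test on lists of 22 genes called 2.5% of 40 simulated pairs with no difference. It called 37.5% with a log2 difference of 2 and 92.5% with a difference of 4. Those lists were drawn from normal distributions of equal spread, and their p was not adjusted over differences. The shares called therefore need not hold for the real lists.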

Results

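Bone-marrow-derived macrophages (BMDM), macrophages grown in culture from mouse bone marrow, were measured by polyA RNA-seq in 1 group of 4 biological replicate libraries from C57BL/6J mice. The sample descriptions state that the cells were exposed to 100 ng/mL Lipid A, the part of lipopolysaccharide that the receptor TLR4 recognises, for 12 h, kept 12 h without it, and exposed again to 100 ng/mL for 60 min. The source names and characteristics call the agent lipoprotein A and leave out the washout, so the labels conflict on both points. Cells that were untreated or treated once are not analysed here, and no level below is a response to the second exposure. Expected counts on genes were 26613690, 23167140, 41453162 and 34946569 in replicates 1, 2, 3 and 4. In all 4 libraries 10407 genes had a TPM (transcript abundance scaled for length and library size) of at least 1, 9704 of them protein coding. Of these genes 1091 had at least 100 TPM in each library. Across those 10407 genes Pearson's r of log2 TPM between pairs of libraries was 0.965 to 0.981, where genes are not independent replicates.

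The 15 most abundant messages included those of ferritin, a chemokine, an acute-phase protein and MHC class I. Fth1, the ferritin heavy chain (ENSMUSG00000024661.7, chromosome 19, 9980598 to 9985098 in mm10), had 58147 ± 8562 TPM (SD, n = 4), and Ftl1, the ferritin light chain, had 18912 ± 1411 TPM. Ccl5, a chemokine that attracts T cells and monocytes (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518), had 20028 ± 3557 TPM. Saa3, an acute-phase serum amyloid A (ENSMUSG00000040026.8, chromosome 7, 46711998 to 46715700), had 18739 ± 4502 TPM. B2m, the light chain of MHC class I, had 14909 ± 740.0 TPM, Lyz2, macrophage lysozyme, had 11353 ± 953 TPM, and the actin-binding Tmsb4x had 15848 ± 2852 TPM. The lysosomal genes Psap, Ctsb and Ctsd had 9023 ± 1608, 8602 ± 559.9 and 7469 ± 1246 TPM, and H2-K1 of MHC class I had 8438 ± 633 TPM. The other genes among the 15 with the highest means were the ribosomal RNA gene CT010467.1, the mitochondrial mt-Atp8 and mt-Co1, and Gm28661, annotated as an unprocessed pseudogene. CT010467.1 (chromosome 17, 39846353 to 39848827) had 71358 TPM in replicate 1 against 27299, 12897 and 26892 in replicates 2, 3 and 4.

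How much of the cytokine and chemokine programme was present after the second exposure was described by list. Among cytokines Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) had 2966 ± 878 TPM (SD, n = 4), Il1b 916 ± 356, Il1a 776 ± 143, the interleukin-1 receptor antagonist Il1rn 322 ± 179 and the anti-inflammatory Il10 132 ± 92.5 TPM. Il6, Ifnb1 and Il12b were far lower, at 38.2 ± 26.8, 26.9 ± 17.4 and 12.8 ± 5.10 TPM. Among chemokines Cxcl10 had 2726 ± 945, Ccl4 2319 ± 1472, Ccl3 2199 ± 1065, Cxcl2 929 ± 411 and the neutrophil attractant Cxcl1 119 ± 74.5 TPM. In all 4 libraries 19 of 26 measured cytokines and 17 of 22 chemokines had at least 1 TPM, and 1 chemokine, Ccl17, had no count in any library. The median chemokine was 2.83 ± 0.60 log2 units (SD, n = 4) above the median cytokine, with log2 medians of 7.69 and 4.86, and was higher in 4 of 4 libraries. The adjusted two-sided permutation p of that difference, from reassigning genes between the lists, was 0.177, and the exact sign-flip p over libraries was 0.13, the smallest that 4 libraries allow. With only members at a mean of at least 1 TPM the difference was 3.25 and the adjusted permutation p 0.0294; with list means in place of medians it was 1.45, and with counts not divided by length it was 1.87.

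Markers of classical (inflammatory) activation stood above those of alternative activation, the state that interleukin-4 induces. The classical genes Saa3, Acod1, which makes itaconate, and Marcksl1 had 18739 ± 4502, 1979 ± 481 and 930.5 ± 309.8 TPM (SD, n = 4), and all 22 measured members reached 1 TPM in each library. Nos2, the inducible nitric oxide synthase, had only 16.9 ± 12.8 TPM, while Ptgs2, the inducible cyclooxygenase, had 94.1 ± 42.3 and the siderophore-binding Lcn2 78.3 ± 34.2 TPM. Of 20 alternative markers 11 reached 1 TPM in each library, led by Tgm2 with 149 ± 52.9, the interleukin-4 receptor Il4ra with 115 ± 23.5 and Tfrc with 64.9 ± 23.5 TPM. Arg1, the arginase of alternative activation, had 0 to 3 counts per library, and Retnla had no count in any. The median classical marker lay 4.12 ± 0.54 log2 units above the median alternative marker, with log2 medians of 5.99 and 1.87, and was higher in 4 of 4 libraries. The adjusted permutation p over genes was 0.00012, and the exact sign-flip p over libraries was 0.13. With only members at a mean of at least 1 TPM the difference was 2.11 with an adjusted permutation p of 0.0602, so the call rests in part on alternative markers that were hardly detected.

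Interferon-stimulated genes formed one of the most abundant groups. Isg15, a ubiquitin-like antiviral protein, had 2964 ± 959 TPM (SD, n = 4), Bst2, which tethers budding viruses, had 2446 ± 464 TPM, and Ifit2 had 2399 ± 479 TPM. All 36 measured members reached 1 TPM and 31 reached 100 TPM in each library, at a log2 median of 8.70 ± 0.31. That median lay 6.83 ± 0.46 log2 units above the median alternative marker, in 4 of 4 libraries. The permutation p over genes was 2e-05, the smallest that 100000 resamples can give, and 6e-05 after adjustment over the 6 differences; the exact sign-flip p was 0.13.

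Inhibitors of the TLR4 response were present beside the receptor pathway itself. The NF-kB inhibitor Nfkbia had 1168 ± 295 TPM (SD, n = 4), Zfp36, which destabilises cytokine messages, had 959 ± 332 TPM, and Tnfaip3, the deubiquitinase A20, had 507 ± 148 TPM. Of 19 reported tolerance regulators 14 reached 1 TPM in each library (log2 median 5.53 ± 0.18). Among them Cd274, which encodes PD-L1, had 529 ± 87.5, Socs3 441 ± 115 and Irak3, an inhibitory kinase of the pathway, 45.1 ± 7.24 TPM. Acod1, given above as a classical marker, is also on this list and was higher, at 1306 to 2447 TPM over the 4 libraries. Among the 28 members of the TLR4 pathway, all at 1 TPM or above in each library, the co-receptor Cd14 had 516 ± 247 and Tlr4 34.05 ± 6.69 TPM, Ikbke had 197 ± 24.6 and Irf5 181 ± 35.2 TPM. The 26 NF-kB feedback regulators, likewise all detected, had a log2 median of 5.79 ± 0.14 against 5.02 ± 0.13 for the TLR4 pathway. The difference of 0.77 ± 0.22 had the same sign in 4 of 4 libraries but did not pass the permutation test over genes (adjusted p 0.261; exact sign-flip p 0.13).

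Immediate-early transcription factors, which are transcribed without new protein synthesis, were led by Junb, Klf6, Egr1 and Atf3. These had 613 ± 198, 511 ± 100.4, 385 ± 129.6 and 352 ± 74.3 TPM (SD, n = 4), and Fos had 76.0 ± 35.5 TPM. In each library 19 of 24 members reached 1 TPM, and the log2 median of the list was 4.88 ± 0.63, from 4.07 in replicate 3 to 5.60 in replicate 4. That was -0.91 ± 0.60 log2 units relative to the NF-kB feedback regulators, with the same sign in 4 of 4 libraries. The permutation test over genes gave an adjusted p of 0.498 and the exact sign-flip test a p of 0.13. With only members at a mean of at least 1 TPM the sign turned, to a difference of 0.025 (permutation p 0.919), while list means gave -1.52 and counts not divided by length gave -1.65.

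The cells carried the messages of macrophages and few of other listed cell types. Of 23 macrophage identity genes 22 reached 1 TPM in each library, with a log2 median of 9.82 ± 0.26 (SD, n = 4), led by Lyz2, Ctsb and Ctsd. Of 82 markers of other cell types 10 did, with a log2 median of -2.49 ± 0.63. The highest of those were Blnk, a signalling adaptor that macrophages also express, at 139 ± 27.8 TPM, and Cd4 at 39.3 ± 10.8 TPM. The median difference of 12.31 ± 0.49 log2 units was found in 4 of 4 libraries, with an adjusted permutation p over genes of 6e-05 and an exact sign-flip p of 0.13; with only members at a mean of at least 1 TPM it was 7.64. Because the median of other cell types lay near 0 TPM, the size depends on the pseudocount, with 9.70 at 1 and 13.76 at 0.01. Members at 1 TPM in each library numbered 3 of 13 for neutrophil markers, 2 of 11 for dendritic cell markers, 1 of 11 for T cell, 2 of 10 for B cell, 1 of 8 for NK cell and 1 of 9 for mast cell and basophil markers. None of 9 erythroid and none of 11 stromal markers did. The neutrophil alarmins S100a9 and S100a8 were uneven, with 71.4 and 49.3 TPM in replicate 1, 61.7 and 34.0 in replicate 3, 6.77 and 5.58 in replicate 2, and 5.10 and 5.69 in replicate 4.

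**Figure D1:**
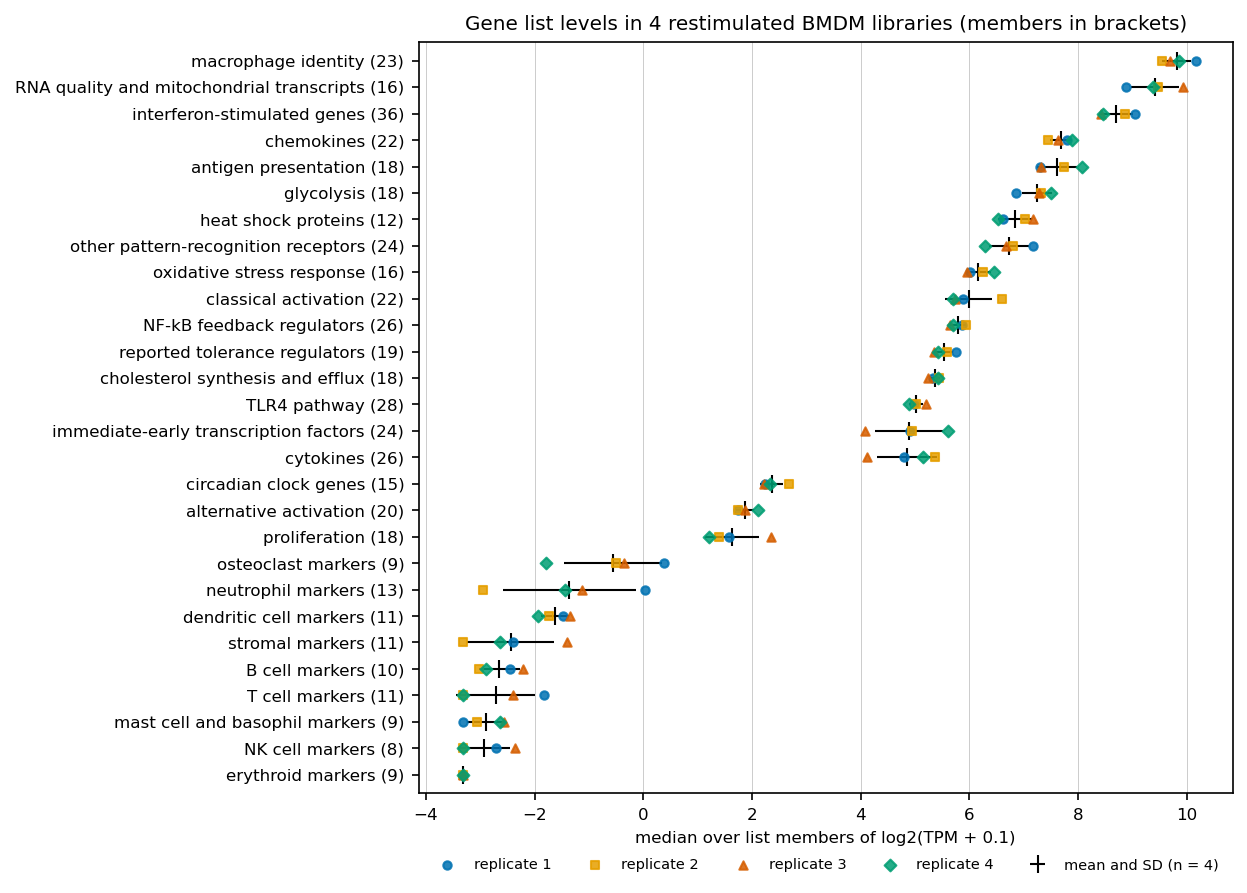
Median log2(TPM + 0.1) of the gene lists in each library, with points for replicates 1 to 4, and the mean and SD over libraries. Macrophage identity, mitochondrial and RNA quality transcripts and interferon-stimulated genes sit at the top, at 9.82, 9.42 and 8.70, and alternative activation at 1.87.

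**Figure D2:**
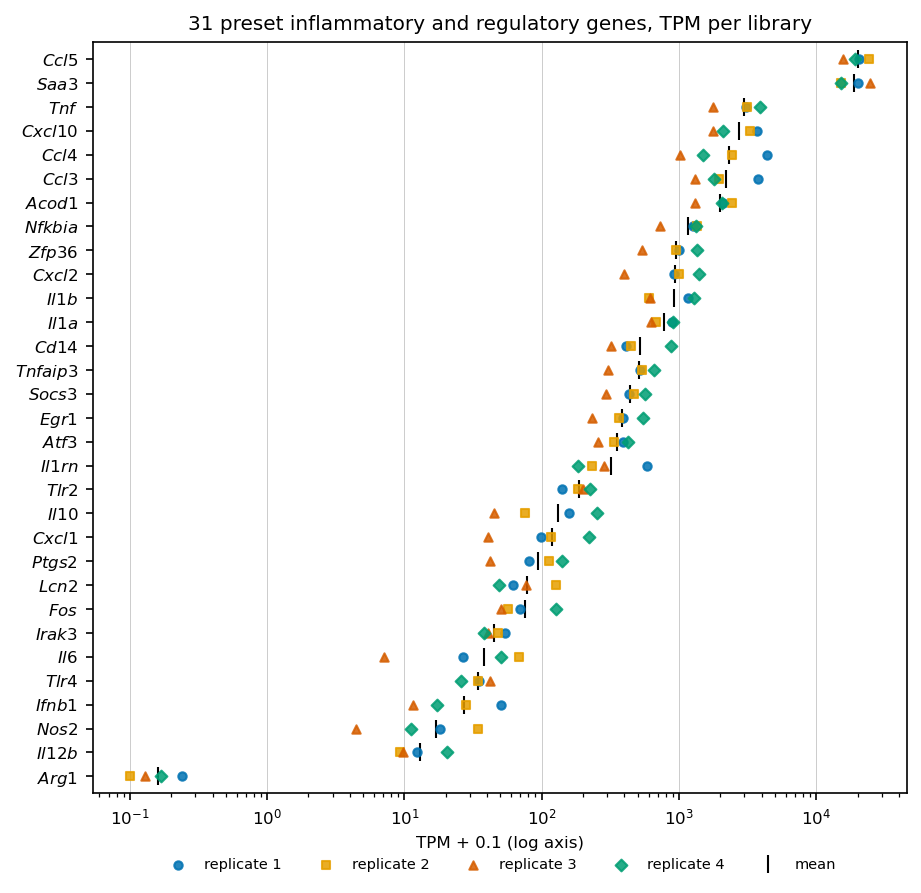
TPM of the genes named in advance, per library on a log axis, with a tick at the mean of the 4 libraries. Ccl5 (20028 TPM) and Saa3 (18739 TPM) have the highest means and Arg1 (0.06 TPM) the lowest.

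Other fixed lists described metabolism, stress and growth. Antigen presentation (17 of 18 members at 1 TPM in each library) had a log2 median of 7.61 ± 0.37 (SD, n = 4), with H2-D1 at 4973 ± 332 TPM. Glycolysis (18 of 18) had a log2 median of 7.24 ± 0.28, with Gapdh at 1232 ± 305 TPM. Pattern-recognition receptors other than TLR4 (23 of 24) had a median of 6.73 ± 0.37, with the glycolipid receptor Clec4e at 738 ± 229 and Tlr2 at 186 ± 35.1 TPM. Heat shock proteins (11 of 12) had a median of 6.84 ± 0.31, with the constitutive chaperone Hspa8 at 1694 ± 72 TPM. The oxidative stress response (14 of 16) had a median of 6.17 ± 0.23, with Prdx1 at 1558 ± 322 TPM, and cholesterol synthesis and efflux (18 of 18) had 5.36 ± 0.10, with Apoe at 5922 ± 2614 TPM. Circadian clock genes (10 of 15) had 2.37 ± 0.21, with Dbp at 25.4 ± 11.7 TPM, and proliferation genes (13 of 18) had 1.63 ± 0.50, with the replication clamp Pcna at 265 ± 57.5 and Cdk1 at 25.6 ± 4.62 TPM. Osteoclast markers (4 of 9) had -0.56 ± 0.90, with Acp5 at 52.4 ± 20.6 TPM. Mitochondrial and RNA quality transcripts (13 of 16) had 9.42 ± 0.44, from 8.88 in replicate 1 to 9.94 in replicate 3. Of the sex-linked genes Xist had 53.9 ± 14.5 TPM, and the 4 Y-linked genes had no count in any library.

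Which genes differed between replicate libraries by more than genes of their abundance do was tested in edgeR. Of 11679 genes 305 passed (adjusted p up to 0.05; 264 protein coding), and Dmpk, a serine/threonine kinase, led them. Dmpk (ENSMUSG00000030409.15, chromosome 7, 19083849 to 19093821) had 60.9 CPM (normalised counts scaled to library size) in replicate 1 against 1.63, 2.47 and 0.673 in replicates 2, 3 and 4 (edgeR adjusted p 4.43e-48). Id3, an inhibitor of helix-loop-helix factors (chromosome 4, 136143497 to 136145755), had 97.0 CPM in replicate 1 against 4.94, 11.1 and 12.7, and the collagenase Mmp13 (chromosome 9, 7272514 to 7283331) had 263 CPM against 33.9, 32.1 and 25.6. The chemokine receptor Ccr3 had 39.1 CPM in replicate 1 against 2.60, 4.30 and 1.49, the cell-cycle gene Ccnd1 389 against 74.2, 85.1 and 86.2, and the metalloprotease Adam8 744 against 142, 191 and 126. Replicate 1 was the farthest library in 192 of the 305 genes, above the others in 126 (41.3%) and below them in 66 (21.6%); among all tested genes it was farthest above in 15.1% and farthest below in 17.3%. Without replicate 1 the count was 135, of which 109 were among the 305; without replicates 2, 3 and 4 it was 212, 204 and 219. Against counting noise alone 9819 genes (84.1%) varied.

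Over all genes, cytokines and chemokines had the highest numbers of variable members. Of 20 tested cytokines 9 passed over all genes and 15 when adjusted over the list alone; of 17 chemokines 8 and 11 did. Both shares exceeded that of other tested genes (Fisher's exact test, adjusted over the lists, 1.90e-08 and 5.67e-08), where genes are not independent. By the same test the share was also higher for classical and osteoclast markers (each 0.00156), immediate-early factors, other pattern-recognition receptors and neutrophil markers (each 0.0113). That test also gave a higher share for mitochondrial and RNA quality transcripts (0.0151), tolerance regulators and proliferation genes (each 0.0184) and interferon-stimulated genes (0.0367). Some lists share members, so these shares are not separate results. The variable tolerance regulators were Il10, Socs1 and Il1rn, of which Il10 and Il1rn are also variable cytokines. Fpr2 counts both as a classical marker and as another pattern-recognition receptor. Il6 had 18.5, 41.3, 4.42 and 30.4 CPM in replicates 1 to 4 (edgeR adjusted p 1.29e-09), Il10 125, 51.2, 31.2 and 179, and Ccl2, a monocyte attractant, 1233, 554, 336 and 226. Nos2 had 53.0, 87.1, 11.4 and 29.8 CPM and was 1 of 5 variable classical markers of 22 (11 adjusted over the list alone). Nr4a1, an orphan nuclear receptor that activation induces early, had 48.9 CPM in replicate 4 against 3.62, 5.24 and 8.02, and was 1 of 4 variable immediate-early factors of 23 (14 adjusted over the list alone). Replicate 3, the lowest library for Il6, Il10 and Nos2, also had the highest mitochondrial share of TPM, 4.77%. Interferon-stimulated genes had 4 variable members of 36, led by Ifit3b (4 adjusted over the list alone).

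The TLR4 pathway, macrophage identity and cholesterol lists had no gene past the threshold in edgeR among 28, 23 and 18 tested, and also none when adjusted over the list alone, by the test in which 910 genes had an unadjusted p under 0.05 and DESeq2's dispersion trend called 336. The numbers over all genes and adjusted over the list alone were 3 and 4 of 26 NF-kB feedback regulators, led by the phosphatase Dusp4, and 3 and 3 of 15 tolerance regulators, led by Il10. They were 4 and 6 of 23 other pattern-recognition receptors, led by the formyl peptide receptor Fpr1, and 3 and 7 of 13 mitochondrial and RNA quality transcripts. For proliferation they were 3 and 4 of 15, for osteoclast markers 3 and 3 of 5, for antigen presentation 2 and 5 of 18, for heat shock proteins 2 and 2 of 11, for the clock 2 and 3 of 14 and for neutrophil markers 2 and 2 of 3. For alternative activation they were 1 and 3 of 13, for oxidative stress 1 and 1 of 15, and for glycolysis 0 and 1 of 18. Mast cell and NK cell markers had 0 over all genes, and 2 of 2 and 1 of 1 adjusted over the list alone. Dendritic, T cell, B cell, erythroid and sex-linked lists had 0 both ways, with 5, 1, 3, 1 and 1 members tested, and no stromal marker was tested.

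**Figure D3:**
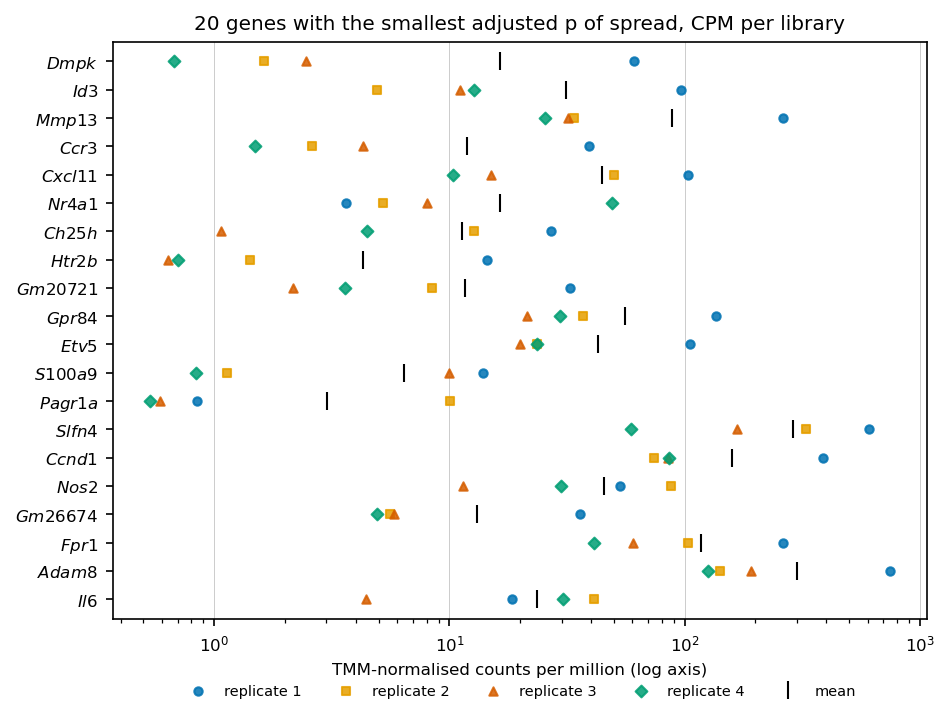
Normalised counts scaled to library size (CPM), on a log axis, of the 20 genes with the smallest adjusted p of spread, with 1 point per library and a tick at the mean. Replicate 1 is the highest library for Dmpk (60.9), Id3 (97.0), Mmp13 (263) and Ccr3 (39.1), and replicate 4 for Nr4a1 (48.9).

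The files record 6 read files for replicates 1 and 2 and 4 read files for replicates 3 and 4, which gave a technical split of 2 libraries against 2. The median interferon-stimulated gene was at -0.40 log2 units and the median classical marker at -0.50 in the libraries with 4 read files relative to the others, while macrophage identity was at 0.08. Mitochondrial and RNA quality transcripts were at a median of 0.38, with 13 of 15 members higher in the libraries with 4 read files. Their list medians, 8.88, 9.48, 9.94 and 9.39 in replicates 1 to 4, did not separate the split, since replicate 2 lay above replicate 4. Nor did those of macrophage identity, at 10.17, 9.55, 9.70 and 9.86. The list medians of interferon-stimulated genes, 9.06, 8.87, 8.43 and 8.45, did separate it. So did those of classical markers, at 5.89, 6.61, 5.74 and 5.71. The order of list medians was not tested. No gene of 12667 passed in edgeR's quasi-likelihood test (lowest adjusted p 0.168), with 897 at an unadjusted p under 0.05, and DESeq2 called 103, of which 86 were lower with 4 read files. When adjusted over the list alone, 2 of 22 classical markers and 2 of 24 cytokines passed in edgeR. Single members passed in the chemokine (18 tested), macrophage identity (23), tolerance regulator (17) and other pattern-recognition receptor (24) lists. The same held for the T cell (1 tested), mast cell and basophil (2) and stromal (6) lists. With 1 or 2 tested members such an adjustment changes p little or not at all. Without replicate 2 edgeR called 13 genes and without replicate 3 it called 2, where 1 arm holds a lone library that is assumed to vary like the other arm. Of the other ways to pair the libraries, that with replicates 1 and 3 together gave 0 genes in edgeR and 106 in DESeq2, and that with replicates 1 and 4 gave 1 and 5.

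Each library has 2 transcript-level quantifications, and their comparison shows which gene levels depend on the quantification. The 31 genes named in advance, among them the cytokines, chemokines and regulators above, depended on it little: 30 had mean TPM within a factor of 2 in both, and Arg1, hardly detected, had 0.06 and 0.145 TPM. Many of the largest differences lay in microRNA genes and pseudogenes. Mir6236, annotated as a microRNA (chromosome 9, 110281287 to 110281409), had 102694 TPM in the second quantification and 0 in the first. The identical microRNA genes Gm23935, Gm24270 and Gm24245 each had 17200 TPM against 0. In the other direction the pseudogenes Gm10222 and Gm10443 had 0 TPM in the second quantification against 1105 and 732 in the first. Of 12299 genes limma called 1340 (adjusted p up to 0.05 and at least 1 log2 unit), 944 higher and 396 lower in the second quantification. These were 204 of 10300 protein-coding genes, 73.2% of processed pseudogenes, 71.0% of snoRNA genes and 68.5% of microRNA genes.

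Of the fixed lists 5 members were called: Il23a at a log2 difference of 1.01, Sigirr at 1.29, mt-Co2 at 3.01, mt-Atp6 at 4.54 and mt-Co3 at 5.76, all higher in the second quantification on average. Il23a was higher in 3 of 4 libraries and the rest in 4 of 4. The count of mt-Atp6 changed by 68688 and 36975 in replicates 3 and 4, where the unprocessed pseudogene Gm10925 changed by -65343 and -34824. In replicates 1 and 2 mt-Atp6 changed by 15021 and 22630 and Gm10925 by -8503 and -14474. How reads were divided between them was not tested. On average mt-Atp8 held 1.60% of TPM in the first quantification and 0.379% in the second, so the mitochondrial share of TPM depends on the quantification. The median gene was at -0.29 log2 units in the second quantification, and at -0.41, -0.59, -0.04 and -0.13 in replicates 1 to 4. With each library centred on its median gene, an alternative chosen after seeing the data, 1102 genes were called, 831 of them higher. Of the 1340 genes 1038 differed in the same direction in each library. The standard errors came from the trend of all genes with level, so a gene as uneven as mt-Co2, with differences from 0.43 to 9.52, could still be called. Without the filter on low values 2145 genes passed and with a minimum of 5 TPM 490 did.

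Most genes with several annotated transcripts were led by the same transcript in each library. This held for 7580 of 9007 protein-coding genes (84.2%) in the first quantification and for 7385 of 8891 (83.1%) in the second. Of 6780 genes with a steady leading transcript in both, 6657 (98.2%) had the same one. Among the genes named in advance, 5 had 2 transcripts above 10% of the gene. Il1rn-201 held 75.1% ± 2.10 (SD, n = 4) of Il1rn and Il1rn-204 15.5% ± 2.72, Tnfaip3-201 held 75.9% ± 7.07 and Tnfaip3-202 17.2% ± 5.52. Zfp36-201 and Zfp36-202 held 81.8% and 18.2% ± 3.16, and Cd14-201 and Cd14-202 held 86.9% and 13.1% ± 2.29. Irak3 was uneven: Irak3-201 held 76.0% ± 24.3, from 49.1% to 97.5%, and Irak3-205 held 21.8% ± 24.4, from 0% to 48.4%.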

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

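The tests of library size and of 1 scaling error for replicate 1, of fewer macrophages for replicate 3, and of short transcripts together with a Klf10 transcript for the quantifications were chosen only after the result was seen. Of 203 results over the 4 libraries, 15 had a library so far from the others that its gap, as a share of the whole range, passed Dixon's critical value at the 95% level. Chance gives about 1 in 20, or 10.15 of 203, and the variable genes were chosen for their spread, so the number alone says little. Replicate 1 stood above the others in 10 of the 15. The gap as a share of the range was 0.970 for Dmpk, 0.915 for Id3, 0.965 for Mmp13, 0.925 for Ccr3, 0.943 for the serotonin receptor Htr2b, 0.864 for Gpr84, 0.957 for Etv5, 0.962 for Ccnd1, 0.971 for Gm26674 and 0.894 for Adam8.

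Replicate 1 was the farthest library in 192 of the 305 variable genes. Library size is argued against, since replicate 2 had the fewest counts and was the farthest in 29. So is 1 wrong scaling of the library as the whole cause, since it moves all genes the same way. The 192 genes lay above the others in 126 and below them in 66. The median tested gene was at -0.19 log2 TPM in replicate 1 relative to the mean of the others. The 192 genes differed there by a median of 1.57 either way. The median gene cannot test a plain scaling error, since TPM has the same sum in each library. Markers of other listed cells cannot decide whether such cells contributed, and 8 of 13 neutrophil markers were highest in replicate 1. The largest excess of any marker over the highest other library was 15.31 TPM, for S100a8. Ccr3 itself had only 17.29 TPM in replicate 1 against at most 2.14, so a small excess excludes nothing. S100a9 was also high in replicate 3, at 61.7 TPM against 71.4 in replicate 1, which keeps its excess small. The highest eosinophil marker in replicate 1, Siglecf, had 0.39 TPM although Ccr3 marks eosinophils. A difference between the cultures, which the labels do not record, stays open, as does RNA quality, since replicate 1 had the highest share of ribosomal RNA (7.29% of TPM against 2.88%, 1.51% and 2.91%) and the lowest mitochondrial share (1.94%); the design has no other group to test a biological difference.

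Replicate 3 was the lowest library in 17 of the 29 variable cytokines, chemokines, classical markers, immediate-early factors and NF-kB feedback regulators, among them Il6, Nos2, Dusp4 and Cxcl2, at a median of -1.39 ± 0.58 log2 TPM (SD over genes) relative to the mean of the others. Of the 17 genes 41.2% separated the libraries with 6 from those with 4 read files. Replicate 4, with 4 read files like replicate 3, was the highest library in 8 of the 17, a count made after the result was seen. That argues against a batch by read files as the whole cause. Because the genes were chosen as lowest in replicate 3, some separate by that choice alone. The share therefore cannot test a batch as part of the cause. The median tested gene was at 0.0909 in replicate 3. It cannot test 1 wrong scaling, since TPM has the same sum in each library. Fewer macrophages would lower their own genes, but the macrophage identity list was at -0.15. That is a smaller fall than in the immediate-early and cytokine lists, close to that of the NF-kB feedback list and larger than that of the chemokine list. The lists of other cells, near the detection limit, were at 0 to 1.39 and exclude nothing. RNA quality stays open, since the mitochondrial and RNA quality list was at 0.69 in replicate 3, as does a difference in the timing or strength of the second exposure, and the design has no other group to test a biological difference.

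The second quantification departed more from the first in replicates 1 and 2, with total counts 1.32 and 1.31 times those of the first against 1.09 and 1.09 in replicates 3 and 4. For the shift of the median gene, the TPM that transcripts shorter than 200 bases take leaves up to 0.20 log2 units unexplained in a library, which argues against these alone. The transcript Klf10-204 (326 bases) had 98376, 99823, 914 and 532 TPM in replicates 1 to 4 of the second quantification and 0 in the first. With it the predicted shift came within 0.11 of the observed one in each library. In replicates 1 and 2 it was -0.406 and -0.600 against -0.413 and -0.592 observed, so these sequences may account for the shift there. In replicates 3 and 4 it was -0.145 and -0.227 against -0.037 and -0.133. The observed shifts there were too small for that margin to decide. The larger total is not that transcript, since without it the ratio was 1.31 and 1.29 in replicates 1 and 2, the higher still 0.22 above the higher of replicates 3 and 4. What else differs between the libraries with 6 and with 4 read files stays open, and no biological explanation was tested.

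Other single results stood apart in the same way. Replicate 3 was the lowest library for Nfkbia (0.870), at 728 TPM against 1271, 1352 and 1320 in replicates 1, 2 and 4. It was also the lowest for Marcksl1 (0.956), at 466 TPM against 1073, 1101 and 1083. Col1a2 of fibroblasts (0.926) was highest in replicate 3, at 1.49 TPM against at most 0.11. It was not alone: of 11 stromal markers 9 were highest in replicate 3, none above 1.49 TPM, and 2 in replicate 1. In CPM Nr4a1 was highest in replicate 4 (0.903) and Pagr1a in replicate 2 (0.968). Pagr1a had 10.1 CPM there against 0.842, 0.589 and 0.533 in replicates 1, 3 and 4. In TPM the difference was smaller, with 18.7 against 5.95, 4.12 and 4.10. Outside the gene comparisons, phiX held 0.139%, 0.293%, 0.0790% and 0.0848% of all counts in replicates 1 to 4, above the 3 counts that a count of 0 allows.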

How the results depend on the processing

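Leaving out ribosomal RNA and mitochondrial genes, centring and untying the variance of the quantifications, and the alternatives for single genes and lists were chosen only after the results were seen. The differences of interferon-stimulated genes over alternative markers and of macrophage over other markers kept their direction and stayed past the threshold under all 11 alternatives each (4.83 to 7.21 and 7.64 to 13.76 log2 units), and that of NF-kB feedback regulators over the TLR4 pathway stayed short of it (0.72 to 0.99). With only members at 1 TPM or more, fewer genes entered: chemokines minus cytokines became 3.25 (adjusted p 0.0294, over a range of 0.0294 to 0.283), classical minus alternative 2.11 (0.0602, range 4e-05 to 0.0602), and immediate-early minus NF-kB feedback genes turned to 0.025 (0.919, range 0.0931 to 0.919). Without each replicate these 3 ranged from 2.60 to 3.08, 3.87 to 4.29 and -1.18 to -0.69.

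Detected genes numbered 7792 to 11245 and genes with a steady leading transcript 6113 to 7942. Variable genes numbered 135 to 219 without each replicate, where fewer libraries were tested, and 9819 against counting noise alone, which leaves out biological spread. The split by read files gave 103 genes in DESeq2, 35 without a filter, and 0 to 13 without each replicate; the cause was not tested. The quantifications differed in 2145 genes without a filter and 490 at 5 TPM or more, where more and fewer genes were tested, and in 1268 to 1325 without each replicate. Of single values, 7 of the 31 fixed genes moved by over 1 SD in the second quantification, and 13 lists did with a pseudocount of 1 and 14 in the second quantification. Without a replicate 56 of 69 variable named genes lost their call at least once, 34 of them without replicate 1; under other settings 15 did, 14 of them with a common dispersion, which kept 214 of the 305 variable genes. Of 21 genes named for the quantifications 4 lost theirs under other settings and 3 without a replicate. Depth limits genes near 3 counts, such as Arg1.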

Other observations

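The neighbours of variable genes and the count of inflammatory genes lowest in replicate 3 were looked at only after the result was seen. Some of the genes highest in replicate 1 lay near each other. Dmwd, which ends upstream of Dmpk on the same strand (chromosome 7, 19076227 to 19082776), had 13.3 TPM in replicate 1 against 3.77, 2.81 and 0.87 in replicates 2, 3 and 4 (edgeR adjusted p 3.52e-09), while Dmpk had 36.0 against 1.64, 2.35 and 0.60 TPM. Other genes around Dmpk, such as Sympk with 53.4, 59.1, 40.3 and 43.8 TPM, did not pass. Ccr1, near Ccr3 on chromosome 9 with the untested Ccr1l1 between them, had 35.9 TPM in replicate 1 against 11.9, 18.3 and 11.5 (edgeR adjusted p 4.63e-05), and Ccr2 did not pass (edgeR adjusted p 0.0750). Pagr1a overlaps Gm42742 on the same strand, which had 17.9, 9.70, 23.6 and 23.5 TPM where Pagr1a had 5.95, 18.7, 4.12 and 4.10. How reads were assigned between both genes was not tested.

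Among genes that did not pass the test of spread, 49 of 78 members of the cytokine, chemokine, classical, immediate-early and NF-kB feedback lists (62.8%) were lowest in replicate 3, against 22.1% of 11296 other genes (Fisher's exact test 1.72e-14, with genes that are not independent and lists picked after the pattern was seen). Among the 17 variable members lowest in replicate 3, replicate 4 was the highest in 8. Of the 3 variable proliferation genes, Mcm5 and Mcm2 were highest in replicate 1, at 57.2 and 43.6 CPM, and Rrm2 in replicate 3, at 7.25 CPM. Of 13 neutrophil markers 8 were highest in replicate 1, with Ngp at 7.96, 0.40, 7.34 and 0.56 TPM in replicates 1 to 4. Of 8 eosinophil markers 3 were highest in replicate 1, none above 0.39 TPM there.

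Osteoclast markers went different ways. Acp5, the tartrate-resistant phosphatase, had 61.6 and 50.8 CPM in replicates 1 and 3 against 24.1 and 28.0 in replicates 2 and 4 (edgeR adjusted p 0.0191). Atp6v0d2, a proton pump subunit, was highest in replicate 3 with 33.1 CPM against 16.2, 10.2 and 18.2 in replicates 1, 2 and 4. Nfatc1, the osteoclast regulator, was lowest in replicate 1, at 12.8 TPM against 22.5, 17.9 and 21.7, and the protease Ctsk in replicate 3, at 1.37 TPM against 2.90, 3.97 and 2.72. The lipid scavenger Cd36 had 303 and 249 CPM in replicates 1 and 3 against 64.5 and 71.3 in replicates 2 and 4 (edgeR adjusted p 2.46e-08). Ciita, the activator of MHC class II, had 17.3 and 18.8 CPM in replicates 2 and 4 against 2.48 and 6.05 in replicates 1 and 3 (edgeR adjusted p 5.95e-06). S100a9, Acp5, Cd36 and, in the opposite direction, Ciita thus set replicates 1 and 3 apart from 2 and 4, a split noticed in these values. Over all genes this split of 2 libraries against 2 gave 0 genes in edgeR, with 907 at an unadjusted p under 0.05, and 106 in DESeq2.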
